A study of Sus scrofa with 19 samples.

How the data were processed

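RNA from the jejunal mucosa of 19 pigs was measured on Affymetrix arrays, 1 array per pig, with a biotin label per the labels' protocols. The labels put 10 pigs in the infected group and 9 in the control group, as separate animals, and name no batch, sex, litter or diet. The values are log2 expression values as the authors deposited them, 1 per probe and pig. The labels do not state their scale, and it was taken from the values, which run from 1.22 to 13.3. Read as natural logarithms, the highest would stand for 597196, above the 65535 that a 16-bit scanner can record. The method of background correction, normalization and summary was not given in the sources used here. The array medians lay between 6.32 and 6.47 and the upper quartiles between 8.09 and 8.16, so the arrays had been brought to a like level but not to identical distributions. The values were used without further normalization.

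Of 16316 probes, 11908 had 1 gene name in the platform annotation, which can be old, 439 had several and 3969 had none listed there. Through gene identifiers and aliases of the RefSeq table, 206 names were updated. No gene was named from a probe with several genes. Where a gene had more than 1 probe (957 of 10849 genes), the probe with the highest mean over all pigs stood for it. Array control probes could not be told from other unnamed probes, so all 16316 were tested. Among them, 644 had values equal to those of another probe in every pig, which leaves 15991 distinct ones. The 185 probes past the threshold in limma hold 181 distinct ones (40 higher, 141 lower).

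Each probe was compared between infected and control pigs with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05 on the adjusted p. Errors of log2 changes are standard errors of that fit. Before the data were examined, 29 gene lists with 600 entries were fixed (cytokine, cell type, metabolic and tissue markers), with the rule for named genes, the tests and most of the alternatives. The rule named the 12 largest rises and the 12 largest falls past the threshold. From each list it took up to 4 members past the threshold, or the 2 with the smallest p where none passed. A set of type 2, type 1, mucus and absorption genes was always given where measured, and 85 genes came out in all. Genes outside the rule are said to have been chosen after their values were seen.

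Lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the 28 lists that qualified. The sex-linked list had 0 measured members and was not tested. The same lists were tested with a correlation estimated from the data and with the rotation test fry, which asks whether a list's genes move, on balance, one way and does not compare them with other genes. List counts are also given adjusted over the list alone. The spread between animals was compared as the share of genes with a higher SD among infected pigs, with a two-sided permutation test of 100 regroupings of values centred within each group. List scores, the mean z-scores of a list's members per pig, were correlated within each group for 4 pairs of lists. Their p-values came from 100000 permutations for the 10 infected pigs and from all permutations, as an exact test, for the 9 control pigs, adjusted over 8 relations.

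The scripts were tested on simulated data for the comparison of infected with control pigs over 16316 probes. A simulated log2 change of 0.5 was recovered for 70.1% of 67 probes, a change of 1 for 98.5% of 67 and a change of 1.5 for 100% of 66, with 13 false calls, and 0 probes were called when nothing was changed. These probes were drawn independently, with the same SD in both groups and no effect shared within a pig, so the rates need not hold for the real pigs. Over 10849 genes, camera recovered 4 of 4 shifted lists and called 1 unshifted list. When the members of unshifted lists were given a shared random effect per pig, as large as their SD between pigs, 47.1% of them had an unadjusted p under 0.05 with the preset correlation and 6.25% with an estimated one. The number of arrays limits the precision.

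The alternatives were quantile normalization, median centring, filters on dim probes, a trended and robust variance, array weights, each pig left out in turn, other thresholds, 1 probe per gene, tissue scores as covariates and the pig number as a block. Numbers on the pigs run through both groups in the labels, and whether they pair pigs was checked. Infected pigs 2, 3, 4 and 9 lay farthest along the first principal component (24.3% of the variance), and fits without them were added after the data were seen, as were correlations of list scores without them, fits to probes with 1 gene name and list medians under each scaling.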

Results

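The jejunal mucosa of pigs was compared between 10 pigs infected with Ascaris suum, the large intestinal roundworm of pigs, and 9 uninfected control pigs. Infection was by trickle dosing of 25 eggs per kg per day from about 4 weeks of age, and a piece of tissue from the middle of the jejunum was taken at day 56. Expression of 16316 probes was measured on 1 array per pig. Correlations between arrays lay between 0.974 and 0.992, and no 2 arrays were close to identical (lowest SD of the difference between 2 arrays, 0.295 log2 units). The comparison addresses which genes and cell types of the mucosa differ after weeks of repeated infection.

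Infected pigs had lower expression of type 1 cytokine and chemokine genes, and a smaller number of genes, TNN, DUOXA2, COL17A1 and TXN among them, were higher. IFNG, which encodes interferon gamma, fell by 1.42 ± 0.24 (log2 change ± SE, adjusted p = 0.0095), from 6.34 ± 0.52 (SD, n = 9) in control to 4.92 ± 0.61 (SD, n = 10) in infected pigs, 2.68-fold lower. The chemokine genes CXCL10, CXCL9 and CXCL11, which interferon gamma induces, fell by 1.47, 1.35 and 1.34 (adjusted p = 0.0320, 0.0467 and 0.0467), in 10 of 10 infected pigs relative to the control mean. The falls were uneven: CXCL10 was 6.64, 6.90, 8.49 and 7.20 in infected pigs 2, 3, 4 and 9, 8.67 to 9.47 in the other 6 and 8.97 to 10.67 in control pigs. In a fit without these 4 pigs, chosen after seeing the data, the changes of CXCL10, CXCL9, CXCL11 and IFNG were -0.82 ± 0.19, -0.81 ± 0.23, -0.73 ± 0.20 and -1.08 ± 0.22 (adjusted p = 0.1204, 0.2211, 0.1851 and 0.1060). TNN, encoding the matrix protein tenascin N, had the largest rise of the named genes past the threshold, 1.76 ± 0.32 (adjusted p = 0.0128, 3.38-fold, higher in 10 of 10 infected pigs), and rose by 0.50 ± 0.12 on its other probe (adjusted p = 0.0467). TXN, encoding thioredoxin, rose by 0.56 ± 0.10 (adjusted p = 0.0095, 10 of 10 pigs).

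In all, 185 of 16316 probes passed the threshold in limma, 40 higher and 145 lower in infected pigs, and 2779 had an unadjusted p under 0.05 where 815.8 would be expected by chance. The changes were moderate, with a median size of 0.52 on the log2 scale and 17 probes changed at least 2-fold. With median centring the split was 53 higher and 113 lower. At 1 probe per gene, 29 genes rose and 84 fell with p adjusted over all probes, and 25 and 78 with p adjusted over these genes alone. Other rises were those of DUOXA2 (1.48), the maturation factor of dual oxidase 2, COL17A1 (1.07), a hemidesmosome collagen, the receptor gene IL20RA (0.82), TNS4 (0.77), SGSM1 (0.57), TRIM3 (0.54) and C15H2orf66 (0.52). Other falls were those of ABI3BP (-1.41), HAPLN1 (-1.13), encoding a hyaluronan link protein, LGI1 (-0.95), SH2D1A (-0.84), encoding a signalling adaptor of T and NK cells, LOC100520753 (-0.83) and MS4A4A (-0.81). The count moved by over 1.5 times when 1 pig was left out: 312, 106, 71, 112, 93, 462, 68 and 335 probes without infected pigs 1, 2, 3, 4, 6, 7, 9 and 10, and 395, 98, 65, 95, 88, 116 and 65 without control pigs 1, 3, 4, 6, 7, 8 and 9. Of the 35 named genes past the threshold, 15 passed it whichever pig was left out: TNN, TXN, TRIM3, COL5A1, IFNG, HAPLN1, LGI1, SH2D1A, IL23R, MS4A4A, HAVCR2, C1QB, C1QC, FLT3 and CD80. The other 20 lost it in at least 1 of the 19 fits, from ABI3BP in 2 fits to GPX2 and IL20RA in 14, and CXCL10, CXCL9 and CXCL11 in 7, 12 and 11. Without infected pigs 2, 3, 4 and 9 none of the 35 passed in limma (0, with 35 at an unadjusted p under 0.05), and 11 had changes over 1.5 times smaller: the 3 chemokine genes, DUOXA2 (0.65), COL17A1 (0.66), GPX2 (0.47), IL20RA (0.47), TNS4 (0.48), TXNRD1 (0.39), ABI3BP (-0.81) and IL7R (-0.55). DUOXA2 was 6.73, 7.49, 7.15 and 6.80 in these 4 pigs, 4.25 to 5.46 in the other 6 infected pigs and 4.04 to 4.65 in control pigs.

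**Figure D1:**
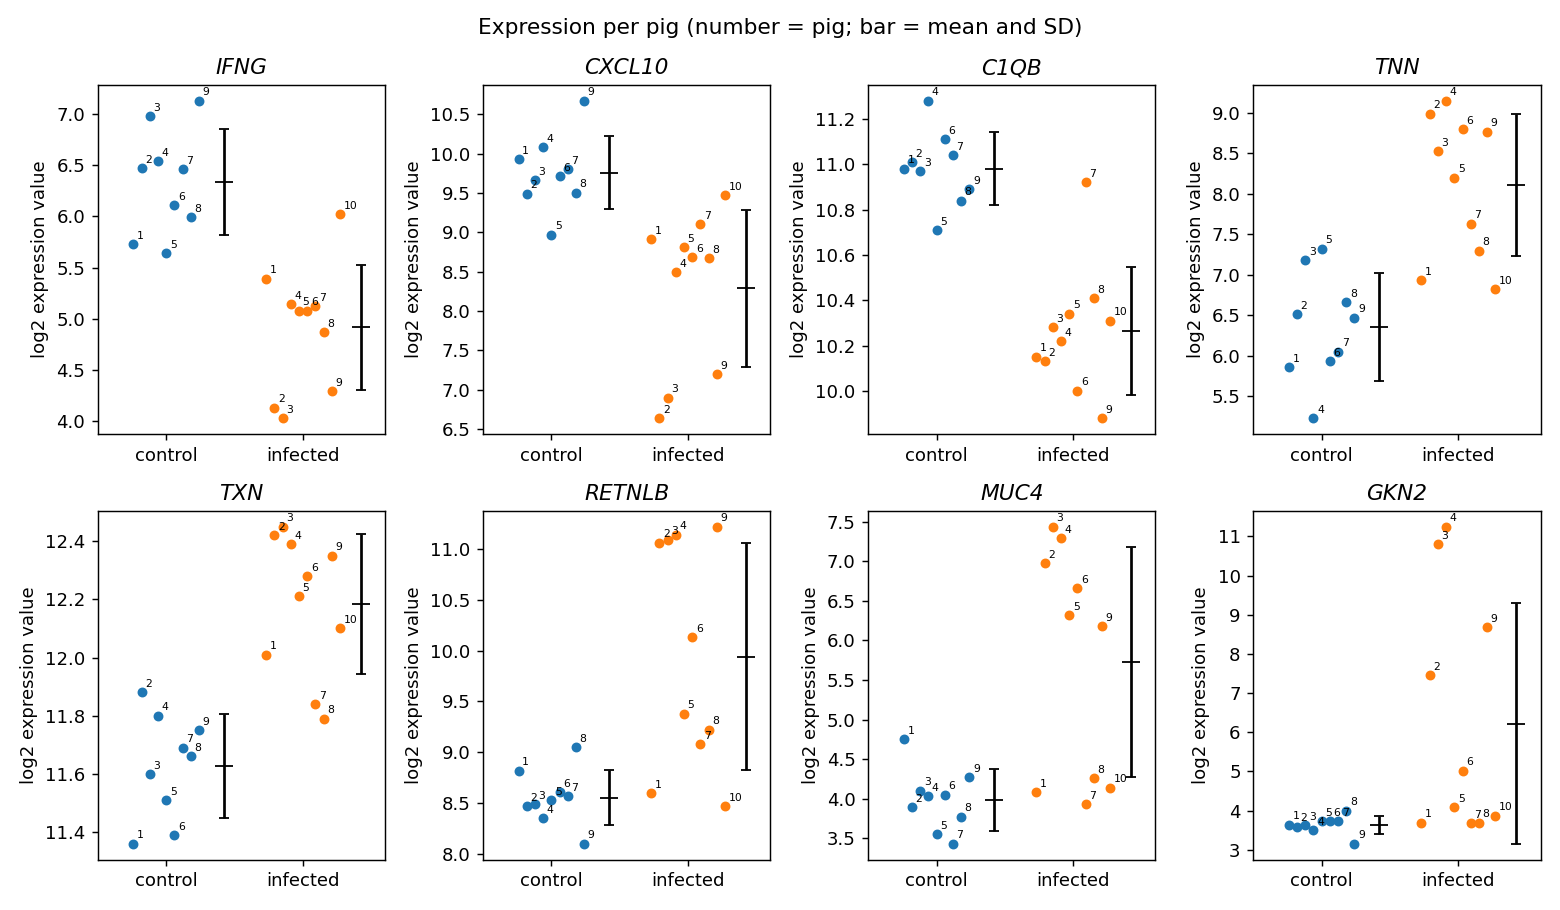
Log2 expression values of 8 genes in each control (blue) and infected (orange) pig, with the pig's number beside each point and the mean and SD as bars. Infected pigs lie lower for IFNG, CXCL10 and C1QB and higher for TNN and TXN, while RETNLB, MUC4 and GKN2 are spread widely among infected pigs and did not pass the threshold.

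Genes of the interferon response were lower as a group. All 24 measured members had a negative log2 change, with a median of -0.60. Scaling by quantiles or by medians kept the sign of the median. Past the threshold, 6 fell, 0 rose and 18 did not pass, and adjusted over the list alone 19 fell. Beside the 3 chemokine genes, IFI44 fell by 0.62 ± 0.14, CMPK2 by 0.58 ± 0.13 and ZBP1, encoding a sensor of nucleic acids, by 0.52 ± 0.12. The list passed in camera (adjusted p = 4.89e-17) and in fry (adjusted p = 0.0071), with adjusted p = 0.0984 with an estimated correlation. Its score was -1.56, -0.99, -0.46 and -1.40 in infected pigs 2, 3, 4 and 9, -0.73 to 0.53 in the other 6 and -0.26 to 1.54 in control pigs. Without these 4 pigs it passed in camera (adjusted p = 2.67e-11) and not in fry (adjusted p = 0.0790).

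Markers of T cells and of cytotoxic and type 1 cells were lower too. In the T cell list 16 of 16 members had a negative change (median -0.48), of which 1 fell past the threshold and 13 fell adjusted over the list alone. That 1 was IL7R, encoding the receptor of the T cell survival factor interleukin 7, at -0.94 ± 0.21 (adjusted p = 0.0327), or -0.55 ± 0.16 (adjusted p = 0.2209) without infected pigs 2, 3, 4 and 9. In the cytotoxic and type 1 list 19 of 20 were negative (median -0.47), and IFNG was the 1 that fell over all probes, against 16 adjusted over the list alone. The T cell list had adjusted p = 8.60e-10 in camera and 0.0400 in fry, and adjusted p = 0.2169 with an estimated correlation. The cytotoxic list had adjusted p = 3.03e-11 in camera and 0.0222 in fry, and adjusted p = 0.1762 with an estimated correlation. The T cell score was -1.37, -1.10, -0.81 and -2.04 in infected pigs 2, 3, 4 and 9, -0.68 to 0.84 in the other 6 and -0.17 to 0.83 in control pigs, and the cytotoxic score was -1.22, -1.06, -0.78 and -1.88 against -0.63 to 0.60 and -0.12 to 1.01. Without these 4 pigs both lists passed in camera (adjusted p = 0.0016 for T cells and 2.44e-04 for cytotoxic cells) and neither in fry (0.3816 and 0.2949).

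Over all probes, the list of macrophage, monocyte and dendritic cell genes held the most changed members, while adjusted over the list alone the interferon, cytotoxic and T cell lists held more. Of 18 measured members 9 fell, 0 rose and 9 did not pass, and 10 fell adjusted over the list alone (median -0.47). The change was negative for 14 members and positive for 4: MRC1 (0.01), CD209 (0.03), CLEC9A (0.11) and FCGR1A (0.13). C1QB and C1QC, encoding chains of complement C1q, fell by 0.72 ± 0.10 (adjusted p = 0.0060) and 0.53 ± 0.10. FLT3, a receptor needed for dendritic cell development, fell by 0.80 ± 0.14, and CD80, a costimulatory ligand for T cells, by 0.66 ± 0.13. In the regulatory T cell and checkpoint list 12 of 12 members were negative (median -0.48). IL10, an anti-inflammatory cytokine, fell by 0.67 ± 0.14 and HAVCR2, an inhibitory receptor, by 0.65 ± 0.13, the other 10 did not pass, and 9 fell adjusted over the list alone. FOXP3, the regulator of regulatory T cells, had a change of -0.47 ± 0.15 (adjusted p = 0.1179). The macrophage list had adjusted p = 8.60e-10 in camera and 0.0032 in fry, and the regulatory T cell list 1.13e-08 and 0.0032. Both lists had adjusted p = 0.0925 with an estimated correlation. Without infected pigs 2, 3, 4 and 9 both passed in camera (adjusted p = 2.10e-08 and 6.34e-06) and neither in fry (0.0516 for each).

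Most measured genes of the goblet, tuft and mast cell lists lay higher in infected pigs, with few single members past the threshold. Of 19 listed tuft cell genes 11 were measured, without POU2F3, DCLK1, TRPM5 and AVIL. Of 16 mast cell genes 7 were, without CPA3, TPSB2, TPSAB1 and CMA1. Changes of the measured genes need not reflect the number of these cells. All 13 measured goblet cell and mucus genes had a positive change (median 0.45). None passed over all probes in limma (0 rose), and 9 rose adjusted over the list alone. MUC4, a membrane mucin, differed by 1.75 ± 0.45 (adjusted p = 0.0555), RETNLB, a secreted goblet cell protein, by 1.38 ± 0.34 (adjusted p = 0.0513), MUC2, the main secreted mucin of the intestine, by 0.53 ± 0.17 (adjusted p = 0.1133) and CLCA1 by 0.45 ± 0.17 (adjusted p = 0.1934). In the tuft cell list 10 of 11 were positive (median 0.36), 0 passed, and 1 rose adjusted over the list alone, SH2D7 at 1.11 ± 0.28 (adjusted p = 0.0511 over all probes). SH2D6 differed by 0.45 ± 0.16 (adjusted p = 0.1648). In the mast cell list 6 of 7 were positive (median 0.27). HDC, the enzyme that makes histamine, rose by 0.60 ± 0.14 (adjusted p = 0.0444; 0.47 ± 0.19 and adjusted p = 0.2180 on its other probe), 6 members did not pass, and 4 rose adjusted over the list alone. The goblet list had adjusted p = 1.13e-06 in camera and 0.0471 in fry, and the tuft cell list 0.0015 and 0.0471. Goblet and tuft cell lists had adjusted p = 0.2578 with an estimated correlation, and the tuft cell list had adjusted p = 0.0512 in fry after quantile normalization. The mast cell list had adjusted p = 0.0017 in camera and 0.0037 in fry, and adjusted p = 0.0925 with an estimated correlation. The goblet cell score was 1.84, 1.57, 0.65 and 1.33 in infected pigs 2, 3, 4 and 9 and -0.67 to 0.40 in the other 6, and the tuft cell score was 0.95, 1.17, 1.53 and 0.55 against -0.55 to 0.07. Without these 4 pigs the goblet and tuft cell lists lost their calls in camera (adjusted p = 0.0531 and 0.2811) and fry (0.4274 and 0.3816), and the mast cell list passed in camera (0.0216) but not in fry (0.0733). The differences of MUC4, RETNLB, MUC2, CLCA1, SH2D7 and SH2D6 were then 0.92, 0.59, 0.26, 0.11, 0.51 and 0.14, and that of HDC 0.43.

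The type 2 cytokine and effector list, many of whose genes mark responses to worms, did not shift in one direction as a whole. Its median change was -0.04, while its mean was 0.12 and camera's direction was up (adjusted p = 0.5159). Of 23 members 0 passed, and adjusted over the list alone 4 rose and 1 fell. IL13, a cytokine that drives mucus production, differed by 0.63 ± 0.19 (adjusted p = 0.0972; 0.25 ± 0.14 without infected pigs 2, 3, 4 and 9) and IL21 by -0.59 ± 0.15 (adjusted p = 0.0547). Values for IL4 (0.23 ± 0.16), IL5 (-0.14 ± 0.13), IL25 (0.18 ± 0.10), IL33 (-0.06 ± 0.16) and CCL26 (0.42 ± 0.27) were within about 2 SE of 0. The eosinophil list had a median of 0.05 and adjusted p = 0.2963 in camera. It held 7 measured of 15 listed genes, without PRG2, CCR3, SIGLEC8, RNASE2 and RNASE3, so it cannot show whether eosinophils changed. Of its 7 members 0 passed and 2 rose adjusted over the list alone, IL5RA (0.33 ± 0.11) and ALOX5 (0.39 ± 0.14), which were 0.26 ± 0.11 and 0.14 ± 0.12 without infected pigs 2, 3, 4 and 9. IL13 was 6.11, 5.69, 5.69 and 5.43 in these 4 pigs, 4.47 to 5.12 in the other 6 and 3.97 to 4.90 in control pigs. EPX, encoding eosinophil peroxidase, differed by 0.04 ± 0.13, at low means of 3.77 in infected and 3.73 in control pigs. The sign of the EPX and IL33 values changed between processing settings.

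Genes of the type 17 list moved in both directions, and 2 genes of the xenobiotic and oxidative stress list rose. In the type 17 and epithelial antimicrobial list IL23R fell by 0.82 ± 0.16 and IL22, a cytokine acting on epithelium, by 0.46 ± 0.11, DUOXA2 rose, and 14 of 17 did not pass (1 rose and 4 fell adjusted over the list alone). IL17A differed by 0.12 ± 0.10 (adjusted p = 0.5825). The list's median was -0.08 (camera adjusted p = 0.2975). In the xenobiotic and oxidative stress list TXNRD1, encoding thioredoxin reductase, rose by 0.73 ± 0.17 and GPX2, a glutathione peroxidase of the gut epithelium, by 0.92 ± 0.23 (0.39 ± 0.11 and 0.47 ± 0.17 without infected pigs 2, 3, 4 and 9, neither past the threshold), while 20 of 22 did not pass (3 rose and 1 fell adjusted over the list alone). Its median was -0.06 (camera adjusted p = 0.8860).

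Absorptive, metabolic and proliferation lists had median changes between -0.15 and 0.24. The measured members of the crypt and proliferation list were cell cycle genes, without the listed stem cell genes LGR5, OLFM4, ASCL2 and SMOC2. The enterocyte list (25 members, median -0.10), the fatty acid oxidation list (13, median -0.12) and the crypt and proliferation list (10, median -0.15) were called lower by camera (adjusted p = 0.0131, 0.0172 and 0.0172), and the cholesterol synthesis list (9, median 0.24) higher (adjusted p = 0.0330). With an estimated correlation their adjusted p = 0.5587, 0.4015, 0.5587 and 0.5587, and fry called none of the 4 (adjusted p from 0.1582 to 0.2942). Without infected pigs 2, 3, 4 and 9 the crypt and proliferation list had adjusted p = 6.91e-06 in camera, lower, and 0.1493 in fry, and the other 3 lists lost their calls. The enterocyte list then pointed up (camera adjusted p = 0.5280), the cholesterol synthesis list down (0.4629), and the fatty acid oxidation list still down (0.4941). None of their members passed in limma (0 of each list), and MTTP, which loads lipid onto lipoproteins, was the 1 enterocyte gene lower adjusted over the list alone (-0.29 ± 0.08, and -0.14 ± 0.07 without these 4 pigs). SI and SLC5A1, encoding the brush border sucrase and the main glucose transporter, differed by -0.14 ± 0.08 and -0.01 ± 0.06 (-0.007 ± 0.07 and 0.016 ± 0.07 without these 4 pigs). Examples of the other lists were ANGPTL4 (-0.66 ± 0.32), HADHB (-0.22 ± 0.11), NSDHL (0.35 ± 0.12), CYP51 (0.24 ± 0.14), TOP2A (-0.25 ± 0.11) and CCNA2 (-0.25 ± 0.12). Without these 4 pigs they were 0.025 ± 0.17, -0.14 ± 0.13, 0.13 ± 0.10, -0.031 ± 0.10, -0.34 ± 0.12 and -0.38 ± 0.13, so ANGPTL4 and CYP51 changed sign.

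Markers of other cell types and segments gave no list call in camera (adjusted p from 0.1137 to 0.8860) or fry. The medians were 0.05 for B and plasma cells, -0.06 for neutrophils, 0.10 for smooth muscle, -0.01 for enteric neurons and glia, 0.13 for fibroblasts and matrix, 0.12 for enteroendocrine cells, 0.01 for tight junctions, 0.03 for immediate early and heat shock genes, 0.05 for blood, 0.13 for proximal and -0.17 for distal gut segment genes, and 0.00 for exocrine pancreas and Brunner glands, whose sign turned under quantile normalization. For blood, the mean (-0.05) and camera's direction (down) differed in sign from the median, and for neutrophils the mean (0.04) differed in sign from the median and from camera's direction (down). Adjusted over the list alone, CD38 fell (-0.28 ± 0.08) among B and plasma cell genes, AQP9 rose (0.72 ± 0.24) among neutrophil genes, CLPS rose among pancreas genes, and 2 fibroblast genes rose and 2 fell. COL5A1, a fibrillar collagen gene, rose by 0.30 ± 0.06 (adjusted p = 0.0188), the 1 member of these lists past the threshold, while its other probe differed by 0.11 ± 0.17 (adjusted p = 0.7847). PIGR, the receptor that carries antibodies into the lumen, differed by 0.32 ± 0.12 (adjusted p = 0.1841), CHGA by 0.44 ± 0.15 (adjusted p = 0.1514), and CLPS, a pancreatic lipase cofactor, by 1.57 ± 0.46 (adjusted p = 0.0892). Without infected pigs 2, 3, 4 and 9 the differences of AQP9, CLPS, PIGR and CHGA were 0.18 ± 0.13, 0.50 ± 0.14, 0.17 ± 0.13 and 0.34 ± 0.18.

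Across the 28 lists, camera with the preset correlation called 12 (4 higher, 8 lower), fry called 8 (3 higher, 5 lower), and camera with an estimated correlation called 0, with 0.0925 as the smallest adjusted p. At an unadjusted p under 0.05 these tests gave 12, 9 and 6 lists. If each test held its nominal rate, 1.40 lists would be expected by chance. Camera with the preset correlation need not hold it. In the simulation 47.1% of unshifted lists with a shared effect per pig had such a p in that test. The simulated effect was as large as a gene's SD between pigs, so this rate need not hold for each list. Estimated correlations of the 12 lists ran from 0.08 (mast cell) to 0.68 (crypt and proliferation). Of 100 splits of the pigs, the real split included, 5 gave at least 12 lists past the threshold in camera with the preset correlation. Its 12 lists can thus not be weighed against 1.40. Infected pigs 2, 3, 4 and 9 lay farthest along the first principal component and were the 4 highest infected pigs for 664 probes. Without them 1 probe passed in limma, camera called 8 lists (1 higher, 7 lower), and fry 0 (5 at an unadjusted p under 0.05). Of the 12 lists, camera then still called the mast cell list higher and the interferon, cytotoxic, T cell, regulatory T cell, macrophage and proliferation lists lower. The goblet, tuft, enterocyte, fatty acid oxidation and cholesterol synthesis lists lost their calls, and the fibroblast list, not called with all pigs, was called lower (adjusted p = 0.0113).

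**Figure D2:**
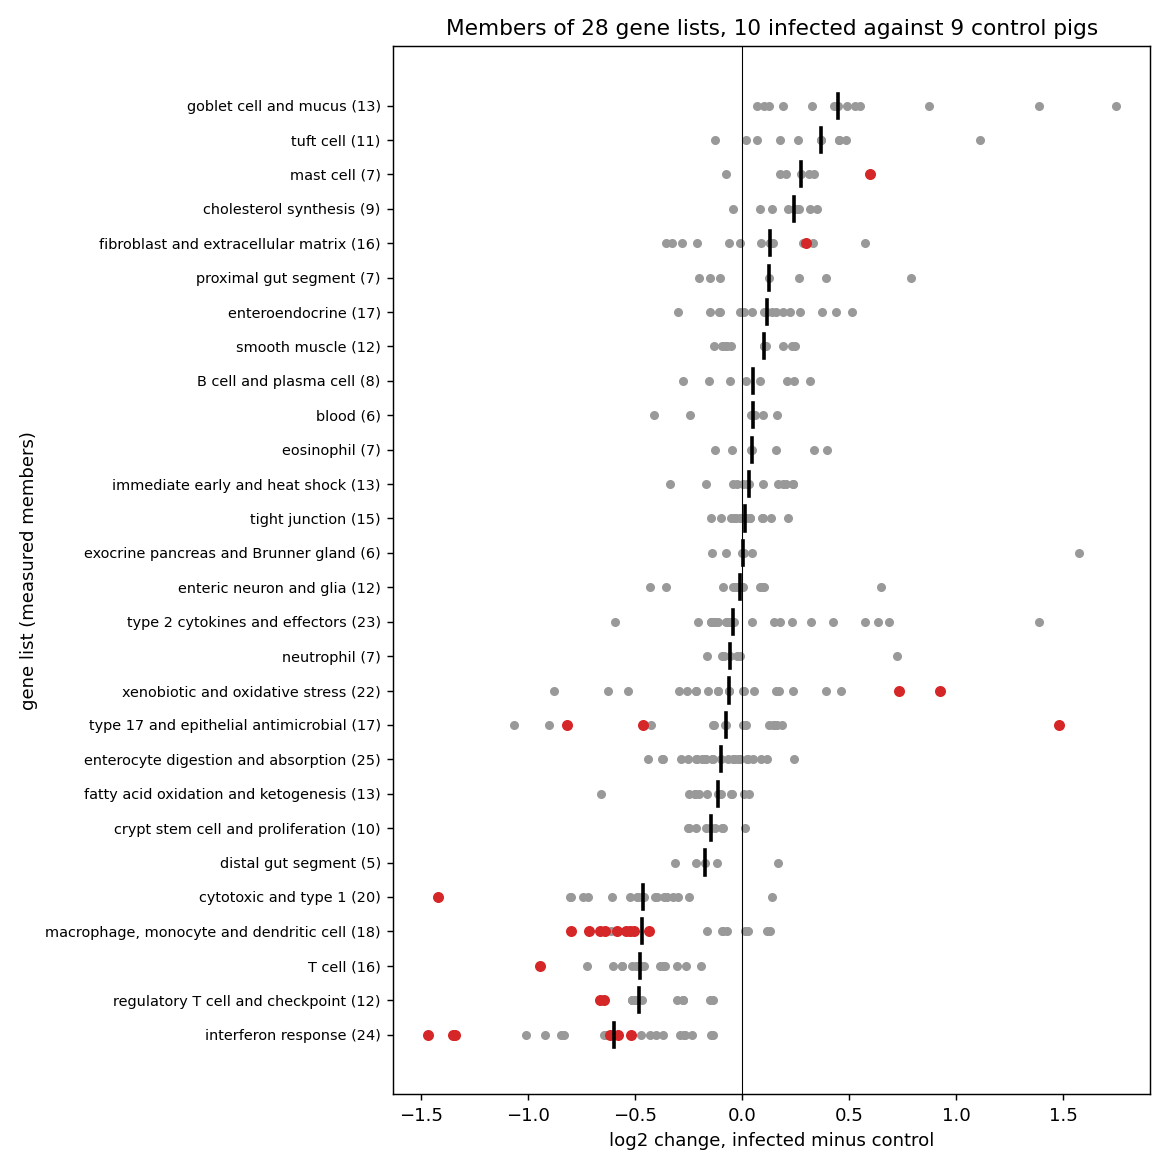
Log2 change (infected minus control) of each measured member of 28 gene lists, with the number of members in parentheses. Red points passed an adjusted p of 0.05 over all probes, grey points did not, and black bars mark list medians, from -0.60 for the interferon response to 0.45 for goblet cells and mucus.

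Most genes had a higher SD among infected than among control pigs. For 7392 of 10849 genes (68.1%) the SD was higher among infected pigs, and the median SD was 0.231 against 0.192 log2 units. In a permutation test 100 regroupings gave 33.8% to 64.6%, so p = 0.0099, the smallest they can give. The widest differences in SD, in genes chosen after their values were seen, were those of GKN2, a gene of the stomach surface epithelium (SD 3.07 against 0.23), LGALS13 (2.31 against 0.27) and the mucin gene MUC1 (1.65 against 0.22). Limma did not call the mean change of GKN2 (2.59 ± 0.92, adjusted p = 0.1550) or MUC1 (1.52 ± 0.50, adjusted p = 0.1286). The share was 69.1% above the median level, where the permutation p was 0.0594, and 58.5% (permutation p = 0.2970) without infected pigs 2, 3, 4 and 9.

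**Figure D3:**
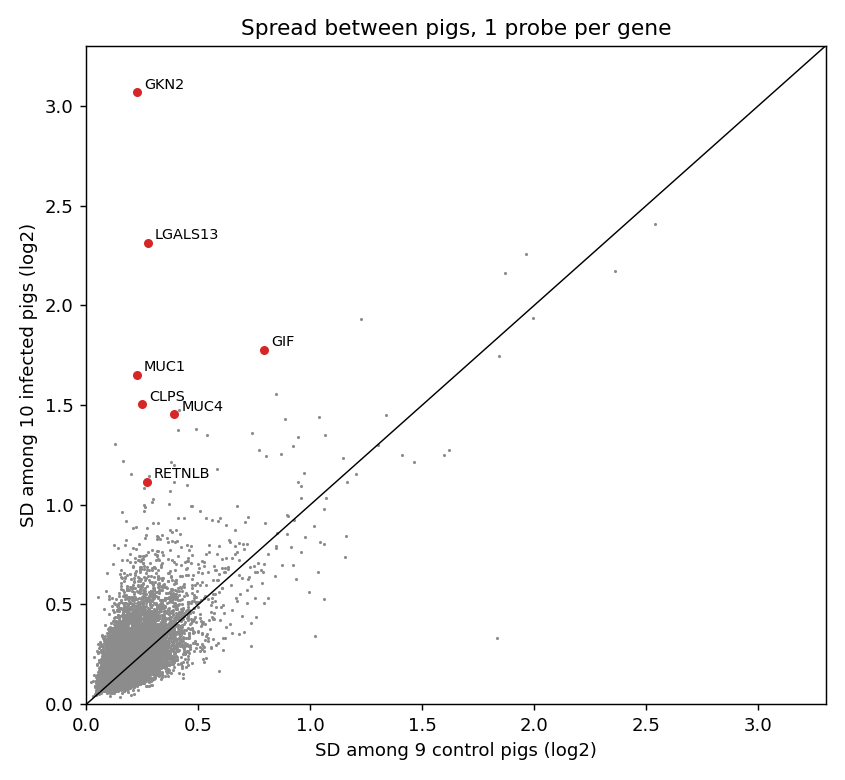
SD among 10 infected pigs against SD among 9 control pigs, in log2 units, with 1 point per gene and a line where both are equal. Most genes (68.1%) lie above the line, and red points mark 7 genes with wide spread among infected pigs, with GKN2 highest at 3.07.

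Of 8 relations between list scores, 4 in each group, 2 passed the threshold, both in the infected group. Tuft and goblet cell scores rose together across the 10 infected pigs, with Pearson's r = 0.77 (permutation p = 0.0118, adjusted p = 0.0474) and Spearman's rho = 0.76 (permutation p = 0.0148, adjusted p = 0.0591). Without the 2 pigs farthest from the median tuft score r was 0.89 (adjusted p = 0.0486). Type 2 and enterocyte scores were inversely related, with r = -0.86 (permutation p = 0.0025, adjusted p = 0.0203), rho = -0.88 (permutation p = 0.0018, adjusted p = 0.0144), and r = -0.81 without the 2 pigs farthest from the median type 2 score (adjusted p = 0.0596 with 8 pigs). Infected pigs 2, 3, 4 and 9, which stood apart in many genes, had the 4 highest tuft and goblet cell scores and the 4 lowest enterocyte scores. In the other 6 infected pigs, a setting chosen after seeing the data, tuft and goblet cell scores had r = 0.27 (exact permutation p = 0.6153) and rho = 0.26 (exact permutation p = 0.6583). Type 2 and enterocyte scores had r = -0.72 (exact permutation p = 0.1069) and rho = -0.71 (exact permutation p = 0.1361) in them, and 0 of 8 relations passed without the 4 pigs. Among the 9 control pigs tuft and goblet cell scores had r = 0.35 (exact permutation p = 0.3535, adjusted p = 0.5657) and rho = 0.20 (exact permutation p = 0.6134), with r = -0.75 without the 2 farthest pigs. Type 2 and enterocyte scores had r = 0.17 (exact permutation p = 0.6751, adjusted p = 0.9001) and rho = 0.48 (exact permutation p = 0.1938), with r = 0.32 without them. The difference between groups was not tested. In infected pigs mast cell and eosinophil scores had r = 0.59 (permutation p = 0.0757, adjusted p = 0.2018) and rho = 0.33 (permutation p = 0.3504), with r = 0.26 without the 2 farthest pigs. Type 2 and eosinophil scores had r = 0.46 (permutation p = 0.1879, adjusted p = 0.3757) and rho = 0.38 (permutation p = 0.2781), with r = 0.25 without them. Neither pair passed in control pigs (exact permutation p = 0.9876 and 0.9738).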

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

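The tests of stomach wall, of pancreas, of shared pigs and covariance against probe noise, of the leukocyte share and of the splits in fry, and the fits without infected pigs 2, 3, 4 and 9, were chosen only after the results were seen. Chance is argued against for the 185 probes, though not excluded. Among 100 splits of the 19 pigs 1, the real one, gave as many, the fewest that the test can give, and the highest of the others gave 1. For the 12 lists of camera chance stays open, since 5 of 100 splits gave as many and the highest other gave 14. For the 8 lists of fry it is argued against in the same way, since 1 of 100 splits, the real one, gave as many and the highest other gave 1.

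A single pig stood far from the rest of its group in 10 of 226 groups of values, where chance flags about 1 in 20 groups, or 11.3. In control pig 1 LGI1 was low at 4.78 and SH2D6 high at 5.41. The blood list's mean z-score was -0.9996 in control pig 6, and that of the distal gut segment list 1.78 in control pig 7. In infected pig 7 C1QB was 10.9, above the 9.88 to 10.4 of the other infected pigs. In infected pig 4 IL22 was 2.93 and NR1H4 7.61. TOP2A was 8.30 in infected pig 10, TRPV6 was 5.85 in infected pig 1, where the others lay between 8.38 and 10.1, and the smooth muscle list's mean z-score was 2.06 in infected pig 3.

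The first pattern weighed is the wide spread among infected pigs, with GKN2 at 7.45, 10.8, 11.2 and 8.68 in infected pigs 2, 3, 4 and 9, 3.67 to 5.02 in the other 6, and 3.15 to 3.99 in control pigs. Stomach wall in the samples is argued against, because the median of 7 stomach genes, 2 of them in other lists, lay between -0.34 and 0.31 log2 units from the control mean in every infected pig (ATP4A 3.94 in infected and 4.01 in control pigs, PGC 2.57 and 2.62), though 1 of the 7, GKN1, a stomach surface gene like GKN2, was 4.97 in infected pig 3 and 4.15 in infected pig 4, against 3.35 to 4.00 in control pigs. Pancreas is argued against likewise, since the median of 4 acinar genes, all of them in the pancreas list, lay between -0.22 and 0.12 from it (PNLIP 2.95 and 3.02, CPA1 4.86 and 4.87), though CLPS, which that list also holds and which is not among the 4, was 8.83, 7.03, 6.83 and 7.74 in infected pigs 2, 3, 4 and 9 against 3.93 to 4.73 in control pigs. Infected pigs 2, 3, 4 and 9 were the 4 highest infected pigs for 664 probes. The most frequent set of 4 control pigs came up for 429, so a frequent set is not particular to infected pigs. In 100 draws that shuffled each probe, which keep no correlation between genes, any set of 4 infected pigs came up for at most 117. Noise of single probes, taken as independent between probes, is thus argued against for the genes that follow the 4 infected pigs. For the wider spread over all genes it stays open, as does a difference between pigs in worm burden or stage of response, which was not tested: the median correlation between 2 probes of a gene differed by 0.0032 between the groups over 957 genes, of which 189 have 2 identical probes, and over the other 768 the covariance of the probes was higher in infected pigs for 59.6% (above 97 of 100 regroupings, which met the one-sided limit first written for this test; after the value was seen that limit was replaced by the two-sided one of the spread test, permutation p = 0.0990).

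The second pattern is the lower level of macrophage, T cell and interferon genes. A scaling difference between arrays is argued against for the macrophage and interferon lists, since 13 of 15 of their members past the threshold passed it under both quantile normalization and median centring. The array medians were already alike, so centring was the weaker test and moved the interferon list's median only from -0.601 to -0.597. The T cell list was not part of that test. Its median was -0.48, and -0.46 and -0.48 under quantile normalization and median centring. A fall shared by the measured genes of the mast cell list is argued against. Their mean level was 0.26 log2 units higher in infected pigs (6.04 ± 0.16 against 5.77 ± 0.11, exact permutation p = 9.42e-04). That of the macrophage list was lower (6.56 ± 0.20 against 6.91 ± 0.10, exact permutation p = 3.68e-04). Both lists had been called before this test was chosen, so its p-values restate those calls. The test does not reach a lower share of the other leukocytes, which stays open. Nor does it settle the number of mast cells, since CPA3, TPSB2, TPSAB1 and CMA1 were not measured. Whether B cells share the fall stays open too, as the level of 4 B cell genes minus that of the macrophage list was 0.39 ± 0.39 in infected and 0.00 ± 0.44 in control pigs, 0.39 apart, with an exact permutation p = 0.0562. A rise of mast cells on their own, fewer cells of some types and lower expression per cell were not tested separately, and all 3 stay open.

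The third pattern is the loss of calls without infected pigs 2, 3, 4 and 9, where 1 probe, of RNF8, passed (log2 change -0.70, adjusted p = 0.0174 in limma, a gene outside the rule). Whether the smaller number of pigs accounts for it cannot be told. When removed, 23 of 100 sets of 4 infected pigs, these included, left as few probes, but the sets can share pigs with these 4. The other sets left 0 to 1527, with a median of 100. Leaving out 1 infected pig gave 106, 71, 112 and 68 probes for pigs 2, 3, 4 and 9. It gave 312, 175, 93, 462, 251 and 335 for pigs 1, 5, 6, 7, 8 and 10, so the number of pigs alone does not set the count. All 185 changes kept their sign without the 4 pigs, at a median of 0.81 times their size. Among the 35 named genes past the threshold with all pigs the ratio ran from 0.44 (DUOXA2) to 1.22 (LOC100520753), and 11 changes were over 1.5 times smaller.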

How the results depend on the processing

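The settings that leave out infected pigs 2, 3, 4 and 9, or keep only probes with 1 gene name, were chosen after seeing the data. Against 185 probes, array weights gave 405, an adjusted p under 0.1 gave 536, at least 1.5-fold 71, an enterocyte score as a covariate 84, 1 probe per gene 103 (fewer tested, p adjusted over them), probes with 1 gene name 101 (fewer tested) and no pigs 2, 3, 4 and 9 gave 1 (fewer pigs). Leaving out 1 pig gave 65 to 462. The cause was not tested except where given. All 185 kept their sign under quantile normalization, median centring, array weights and each pig left out, and 165 and 151 of them stayed past the threshold under the first pair. With the pig number as a replicate block, which leaves out infected pig 10, 56 passed, 47 of them among the 185. The values gave no sign that the numbers pair the pigs. Deviations from the group mean of each probe had correlations of -0.10 to 0.07 between same-numbered pigs, 0 of 9 over 0.1. In these deviations 1 of 9 infected pigs correlated best with the control pig of its own number. A pairing in the design that left no trace in expression cannot be excluded this way. Of 35 named genes past the threshold, 35 passed under quantile normalization, 33 under median centring, 31 with a trended and robust variance, 35 with array weights, 10 with the block and 0 without pigs 2, 3, 4 and 9.

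For the lists, 0 passed in camera with an estimated correlation and 0 in fry without the 4 pigs. Other settings gave 8 to 13 lists, 11 with the block, and leaving out 1 pig gave 11 to 13. Without the 4 pigs camera's direction turned for enterocyte (adjusted p = 0.5280), cholesterol synthesis (0.4629), smooth muscle (0.1531), neuron and glia (0.9052), fibroblast (0.0113, lower), immediate early and heat shock (0.5280), blood (0.8723) and proximal segment (0.2811) lists. The share of genes with a wider spread was 69.1% above the median level (permutation p = 0.0594), 58.5% without the 4 pigs (permutation p = 0.2970), and 66.2% to 72.4% with 1 pig left out. Of the 2 relations between list scores 1 passed without the 2 pigs farthest from the median, tuft with goblet, and 0 without the 4 pigs (6 infected pigs left). With each of 45 pairs of infected pigs left out, r was -0.95 to -0.79 for type 2 with enterocyte and 0.65 to 0.93 for tuft with goblet. Of the named genes 5 changed sign without the 4 pigs: ANGPTL4 went from -0.66 to 0.025, CYP51 from 0.24 to -0.031, SMTN from 0.19 to -0.083, EPX from 0.04 to -0.068 and SLC5A1 from -0.01 to 0.016. EPX was -0.0011 under quantile normalization and IL33 was 0.0089 with the block. With 1 pig left out IL33 ran from -0.14 to 0.0089, EPX from -0.041 to 0.088 and SLC5A1 from -0.038 to 0.0044. Background signal was not used here, so low values such as IL4, IL5 and EPX could be near it. The same holds for IL22, which passed the threshold with means of 3.43 in infected and 3.89 in control pigs.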

Other observations

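Several genes outside the fixed rule, chosen after their values were seen, passed adjusted over the list alone and not over all probes. Among cytotoxic and T cell genes KLRK1 (-0.81), an activating receptor of NK cells, GZMH (-0.80), a granzyme gene, CXCR6 (-0.74) and CD8A (-0.73) were lower on the log2 scale, and so were the interferon response genes OASL (-1.01) and GBP2 (-0.92). NOS2 (-1.07), encoding inducible nitric oxide synthase, and SAA3 (-0.90), an acute phase gene, were lower in the type 17 and antimicrobial list. KIT (0.34) and GATA2 (0.31), a receptor and a transcription factor of mast cells, were higher, as were CREB3L1 (0.87) and AGR2 (0.55) in the goblet cell list and IL17RB (0.68), encoding a receptor chain for interleukin 25, and POSTN (0.57) in the type 2 list. Without infected pigs 2, 3, 4 and 9 all 14 kept their sign, and KLRK1 (-0.38), GZMH (-0.41), CD8A (-0.35), GBP2 (-0.44), NOS2 (-0.63), CREB3L1 (0.34), AGR2 (0.12), IL17RB (0.24) and POSTN (0.30) were over 1.5 times smaller.

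Other genes outside the rule, also chosen after their values were seen, followed the same infected pigs as GKN2. GIF, which encodes the vitamin B12 carrier intrinsic factor, was 9.97, 9.96, 9.94 and 10.1 in infected pigs 2, 3, 4 and 9, 6.26 to 7.05 in the other infected pigs and 4.45 to 6.60 in control pigs. PNLIPRP2, a lipase relative, was 12.1, 11.9, 11.8 and 12.2 in these pigs. Over all probes, pigs 2, 3, 4 and 9 were the 4 highest infected pigs for 664 probes, against 77.7 if probes were independent, which they are not. The most frequent set of 4 control pigs came up for 429, against 129.5.

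The test on SLC2A2 was chosen after its split was seen. In all, 3 probes split the pigs of both groups by a gap of over 3 log2 units with at least 3 pigs on each side. That of SLC2A2, a glucose and fructose transporter gene, had a gap of 4.29 and was high in 6 of 10 infected and 3 of 9 control pigs (Fisher's exact p = 0.3698). That of IGSF5 was high in 7 of 10 and 6 of 9 pigs, and that of UQCR10 in 3 of 10 and 1 of 9. A sequence variant under 1 probe is a candidate explanation for SLC2A2, since the gene's other probe ranged over 0.16 log2 units across the 19 pigs. No sequence was examined.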
